A study of Mus musculus with 6 samples.

How the data were processed

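The study profiled 4MOSC1 mouse oral squamous carcinoma cells by RNA sequencing in 6 libraries, 3 unstimulated and 3 stimulated with TNF-α and IFN-γ. Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA was removed and cDNA libraries were made from the fragmented remainder. The protocol text describes extraction from ground tissue, whereas the labels name a cell line as the source of every sample. The libraries were grouped by their titles, which also carry the replicate numbers. Columns of the table were matched to libraries by group and replicate number, and 0 columns of values were left unused.

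The authors deposited one table of 17207 genes with TPM (a length-corrected share of the library's transcripts, scaled to a fixed total) in 1 column per library, rounded to 2 decimals, per the file headers and values. The submitters' processing notes name HISAT, Bowtie2 and the mouse build GRCm38.p6. Their versions and roles, the quantification tool, the annotation and any filter on genes are not given in the sources used here. TPM values are relative to the sum over all genes in a library, so genes that take a larger share lower the values of the others. They keep neither counts nor depth, and no counting interval or detection limit could be given. For the same reason no model of read counts was run.

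The table names genes by identifiers made of a fixed prefix and a number. None of the 17207 identifiers was found in the reference tables of gene names, RefSeq genes and GENCODE annotation. The number after the prefix equalled a RefSeq gene number for 16.9% of genes. After shifting the numbers by up to 50 in either direction, this share was 16.5% to 17.3%, so the match lay within what unrelated numbers give. Fold changes of genes with neighbouring numbers were not correlated beyond chance (Pearson's r = 0.0096 across 11622 genes, permutation p = 0.27, 1000 permutations). The identifiers were therefore used as they stand, no coordinates are given, and the 36 gene lists that had been fixed before the data were examined, among them lists for pyroptosis, interferon response and cell type markers, could not be applied. Any RNA of other cell types was likewise not assessed.

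Genes with at least 1 TPM in at least 3 of the 6 libraries were tested (11622 genes), and 5585 were not. The values were taken as deposited, without further scaling, as log2(TPM + 1), and compared with limma 3.58.1 (R 4.3.3) using a linear model with the group as its only term, empirical Bayes moderation with a mean-variance trend and robust settings. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p under 0.05. Fold changes are cytokines minus control on the log2(TPM + 1) scale with their standard errors, and ratios of mean TPM are given where named as such. Mean levels of classes of genes and the number of genes listed at 0 were compared with exact permutation tests in scipy 1.17.1. Shares of the TPM total were not tested. Genes were assigned to level classes by their mean over all 6 libraries.

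The rule for the genes to be named was set before the data were examined. It ranked called genes by fold change, required that the values of the groups did not overlap and that the higher group had a mean of at least 5 TPM, and left out entries without a symbol. As no entry has a symbol, that last condition would have removed every gene. The ranking was kept. Only the first 2 genes in each direction are given, fewer than the rule had set, out of 1949 that rose and 2916 that fell. The rule's other parts, which name genes by symbol, could not be applied.

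The procedure was tested on simulated data with the levels of the real genes and 200 genes changed by known folds among 11622 simulated genes. Each gene's variance was the average of its own and the median variance, with independent normal noise. For this comparison it recovered 44.9% of genes changed 1.25-fold, 92% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold. Of the 181 calls in the simulation, 15 (8.29%) were unchanged genes, out of 11318 unchanged genes tested. In the real data 51.5% of the tested genes were called, far more than were changed here, so these shares need not carry over.

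The alternatives were a replicate block, pseudocounts of 0.1 and 0.01, no filter, a filter at 5 TPM, quantile normalization, median ratio scaling, limma without trend and robust settings, a test against a 2-fold change (limma's treat) and leaving out each library in turn. All of these were chosen before the data were examined. The level classes, their variants and the counts among genes with a mean of at least 10 TPM were chosen after seeing the data.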

Results

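The series measured gene expression in 4MOSC1 cells, a mouse oral squamous carcinoma cell line, by RNA sequencing of total RNA. Cells that received no cytokine (3 control libraries) were set against cells stimulated with TNF-α and IFN-γ at 25 ng/mL each for 48 h (3 cytokine libraries). Both cytokines are secreted by activated T cells. The series concerns pyroptosis, a lytic cell death, in head and neck squamous carcinoma, and the comparison addresses which transcripts of the tumour cells themselves change on exposure to these cytokines. Expression was given for 17207 genes as TPM, a length-corrected share of a library's transcripts scaled to a fixed total. The columns of the 6 libraries summed to between 999999.24 and 1000000.47, so the read depth behind the values is unknown. The labels do not say whether the libraries came from separate cultures, and the p-values then measure only the spread between these libraries, which may be technical.

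The genes carry identifiers that the sources used here do not pair with gene names. No statement can therefore be made about gasdermins, caspases, interferon-stimulated genes, antigen presentation or any other named gene or pathway, and the response is described by the number, direction, size and expression level of the genes that changed. Only the 2 leading genes in each direction are given, under the identifiers of the table.

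The 2 groups separated clearly. Over the 11622 genes that reached 1 TPM in at least 3 libraries, Pearson's r of log2(TPM + 1) across genes was 0.995 to 0.996 between control libraries and 0.995 to 0.997 between cytokine libraries. Between a control and a cytokine library it was 0.952 to 0.962. Genes are not independent replicates, so these coefficients describe the libraries and are not tests. The first principal component held 87.1% of the variance and parted the groups, with scores of -33.1 to -28.1 in the controls and 28.8 to 31.8 in the cytokine libraries.

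A large part of the detected transcriptome differed between the cytokine and control libraries. Of the 11622 genes tested, 5989 (51.5%) were called at a Benjamini-Hochberg adjusted p under 0.05 in limma's moderated test, 2237 of them higher and 3752 lower with the cytokines. Most changes were small. The median rise among the called genes was 1.32-fold and the median fall was also 1.32-fold, and 4378 of the called genes (73.1%) moved by less than 1.5-fold. On the log2(TPM + 1) scale of the fit, large changes were mostly increases: 329 called genes were at least 2-fold higher and 153 at least 2-fold lower. At least 4-fold changes comprised 117 rises and 5 falls, and 36 genes rose and 0 fell by at least 16-fold. The added 1 TPM understates changes that have a low value in either group. When each library was first divided by its median ratio to the average library, which sets the change of the typical gene near 0, 2999 calls were higher and 3159 lower. With a pseudocount of 0.1 in place of 1 the order at 2-fold turned, with 393 genes at least 2-fold higher and 427 at least 2-fold lower, while rises still outnumbered falls at 4-fold (166 and 30) and at 16-fold (57 and 2).

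**Figure D1:**
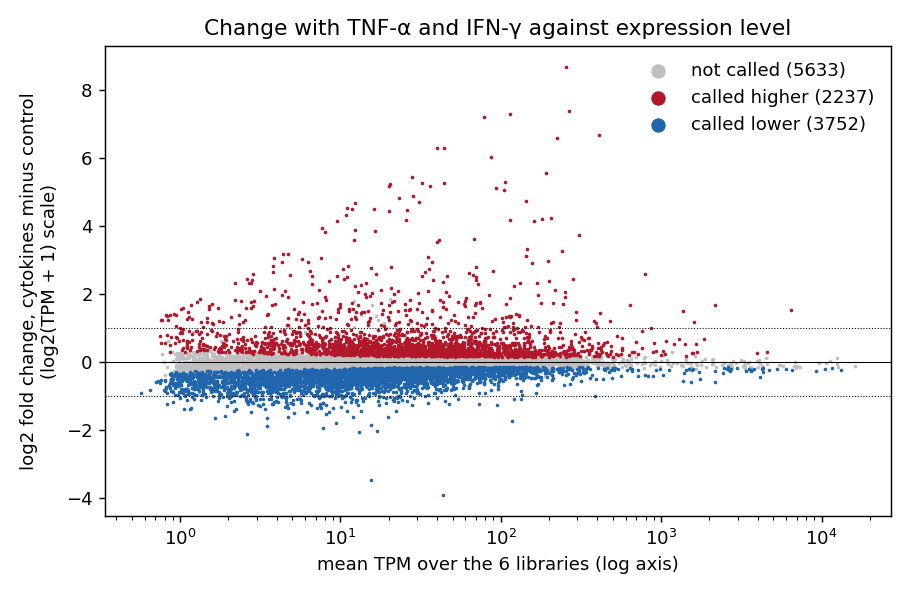
Each point is 1 of the 11622 tested genes, with its mean TPM over the 6 libraries on a log x axis and its log2 fold change, cytokines minus control, on the y axis (log2(TPM + 1) scale); red, blue and grey mark genes called higher, called lower and not called, and dotted lines mark a 2-fold change. On this scale 36 called genes rose and 0 fell by at least 16-fold.

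Ranked on the log2(TPM + 1) scale, which shrinks changes from or to low values, so that ratios of means would rank genes otherwise, the first gene among the rises was G10090_2998. It was at 0.270 ± 0.056 TPM in the controls and 512 ± 41 TPM with the cytokines (SD, n = 3 each), a 1897-fold ratio of means. Its log2 fold change was 8.66 ± 0.07 (SE), with an adjusted p of 2.6e-17 in limma. The second was G10090_15535, which went from 2.22 ± 0.42 to 533 ± 23 TPM (SD, n = 3 each), a 240-fold ratio, with a log2 fold change of 7.38 ± 0.09 (SE) and a limma adjusted p of 8.8e-16. First among the falls on the same scale was G10090_21514, which went from 82.9 ± 15.1 to 4.54 ± 0.29 TPM (SD, n = 3 each). Its control mean was 18.3 times its cytokine mean, and its log2 fold change was -3.91 ± 0.11 (SE; limma adjusted p = 8.9e-12). G10090_18215 fell from 29.2 ± 4.3 to 1.70 ± 0.31 TPM (SD, n = 3 each), with a control mean 17.2 times the cytokine mean and a log2 fold change of -3.48 ± 0.11 (SE; limma adjusted p = 2.2e-11). Across all tested genes the values of the groups did not overlap for 59.2%, against 10% by chance with 3 libraries per group.

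**Figure D2:**
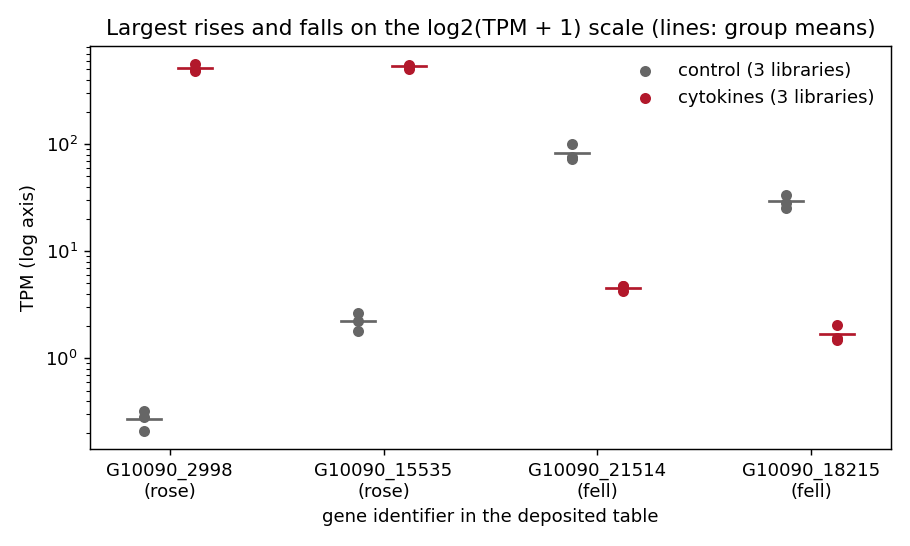
TPM on a log axis in each of the 3 control (grey) and 3 cytokine (red) libraries for the 2 genes with the largest rise and the 2 with the largest fall on the log2(TPM + 1) scale; short lines are group means. G10090_2998 lies between 0.21 and 0.32 TPM in the controls and between 478.51 and 557.74 TPM with the cytokines.

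A small set of genes went from near absence to clear expression. There were 20 genes under 1 TPM in every control and at 10 TPM or more in every cytokine library. All 20 were called higher, which this choice of genes largely fixes in advance. Their median level with the cytokines was 28.3 TPM and the highest was 512 TPM. One of the 20 was listed at 0 in all 3 controls. No gene made the opposite move from at least 10 TPM in every control to under 1 TPM in every cytokine library. With 1 TPM as the limit on both sides, 106 genes crossed it upward in every library and 197 crossed it downward.

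The called genes also differed in how much of the transcript pool they held. The 2237 genes called higher made up 13.7 ± 0.7% of the TPM total in the controls and 20.9 ± 0.3% with the cytokines (SD, n = 3 each). The 329 genes at least 2-fold higher rose from 1.41 ± 0.10% to 4.89 ± 0.18% of the total, so they held 3.47 of the 7.15 percentage points gained. The 3752 genes called lower went from 30.0 ± 0.5% to 24.3 ± 0.2%. The 5633 tested genes that were not called also held less with the cytokines, 54.80 ± 0.09% against 56.17 ± 0.19% in the controls (SD, n = 3 each). The 153 genes at least 2-fold lower were a minor part of the pool, at 0.280 ± 0.007% and 0.107 ± 0.002%. The 10 genes with the largest gain in TPM held 22.5% of the gain and the 10 with the largest loss held 22.4% of the loss. The first 50 held 42.6% of the gain and 48.0% of the loss, and the first gene alone 8.69% and 3.97%. These sets were chosen by their change in the same libraries, so their shares describe the response and are not tests of it.

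The direction of the calls differed between expression levels. Among the 3475 tested genes with a mean under 10 TPM over the 6 libraries, 494 were called higher and 1445 lower, and the median log2 fold change was -0.19. Among the 6758 genes from 10 to 100 TPM, 1363 were higher and 2011 lower. In the 1258 genes from 100 to 1000 TPM the order turned, with 362 higher and 257 lower, and 65 of the rises against 3 of the falls were at least 2-fold. The class mean includes the cytokine libraries, so a gene that rose strongly can enter this class through its level with the cytokines. G10090_2998, at 0.270 TPM in the controls, is in it. The excess of rises therefore need not hold for genes already at this level in the controls. Of the 131 genes over 1000 TPM, 18 were higher and 39 lower, and the largest fall among them was a log2 change of -0.60. Falls outnumbered rises under 10 TPM under both other scalings as well, with 592 higher and 1313 lower after median ratio scaling and 730 higher and 1105 lower after quantile normalization, though the median log2 fold change shrank to -0.140 and -0.064. Above that level the order differed between scalings. From 10 to 100 TPM median ratio scaling gave 1925 higher and 1668 lower, and quantile normalization 1505 higher and 2125 lower. From 100 to 1000 TPM they gave 462 higher and 166 lower, and 267 higher and 450 lower. Over 1000 TPM they gave 20 higher and 12 lower, and 15 higher and 24 lower. Median ratio scaling sets the change of the typical gene near 0, so it does not decide the direction. Quantile normalization gives every library the same distribution of values, which also shifts the balance of rises and falls, so it does not decide the direction either. From 100 to 1000 TPM the median log2 fold change was 0.011 as deposited and -0.084 after it.

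The weakest genes, most of which were not tested, were lower as a class with the cytokines. The mean level of the 2362 genes with a mean from 0.1 to 1 TPM was 0.441 ± 0.018 TPM in the controls and 0.330 ± 0.028 TPM with the cytokines (SD, n = 3 each), and 70.6% of these genes had the lower mean in the cytokine group. That share was 62.3% under 0.1 TPM, 67.6% from 1 to 10 TPM and 55.6% from 10 to 100 TPM. It was 47.6% from 100 to 1000 TPM and 72.5% over 1000 TPM, so it was not particular to weak genes. The 3322 detected genes under 0.1 TPM went from 0.0379 ± 0.0012 to 0.0256 ± 0.0050 TPM (SD, n = 3 each). The deposited values are rounded to 2 decimals, so levels in this class lie close to the rounding step. The ratio of cytokine to control class means was 0.674 ± 0.132 under 0.1 TPM, 0.748 ± 0.062 from 0.1 to 1 TPM, 0.896 ± 0.027 from 1 to 10 TPM, 1.004 ± 0.015 from 10 to 100 TPM, 1.080 ± 0.009 from 100 to 1000 TPM and 0.957 ± 0.013 over 1000 TPM (SD over the 3 cytokine libraries). Genes that rose strongly can raise the ratio of a class that they entered through their level with the cytokines. After median ratio scaling the ratios of the 3 lowest classes were 0.701 ± 0.126, 0.779 ± 0.053 and 0.934 ± 0.015, while the others were 1.047 ± 0.003 from 10 to 100 TPM, 1.126 ± 0.018 from 100 to 1000 TPM and 0.997 ± 0.029 over 1000 TPM (SD over the 3 cytokine libraries). In the values as deposited, 5 of the 6 classes had groups that did not overlap, which gave an exact two-sided permutation p of 0.1 each, the smallest that 3 libraries against 3 allow (0.12 after Benjamini-Hochberg adjustment over the 6 classes). The class from 10 to 100 TPM did not differ beyond the spread of the libraries as deposited (exact permutation p = 0.9). After median ratio scaling all 3 cytokine libraries had ratios of 1.044 to 1.051, but the scaled ratios were not tested. That shift comes from the scaling factors, which move every class of a library alike, so it decides nothing about this class. The number of genes listed at 0 was 1773 ± 14 in the controls and 2189 ± 170 with the cytokines (SD, n = 3 each; exact two-sided permutation p = 0.1). Because of the rounding, a value listed at 0 can stand for a level too small to show.

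**Figure D3:**
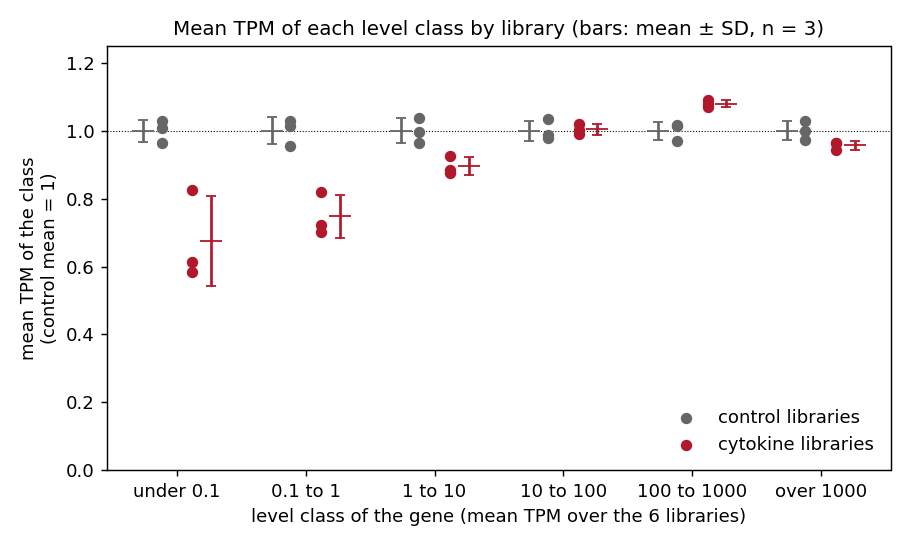
Mean TPM per gene in 6 classes of expression level, relative to the control mean of the class, for each control (grey) and cytokine (red) library; bars give the mean ± SD of each group (n = 3). The cytokine libraries lie below all controls in the 3 lowest classes, at mean ratios of 0.674, 0.748 and 0.896, and above them from 100 to 1000 TPM. Classes are set by the mean over all 6 libraries, so genes that rose strongly can enter a class through their level with the cytokines.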

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

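The alternatives here were chosen before the data were examined, except those on level classes and on genes with a mean of at least 10 TPM, which were chosen after. Of 78 counts of genes under an alternative, 69 stayed within 1.5 times the reported count. A test against a 2-fold change, a stricter criterion by construction, called 239 genes, 214 higher and 25 lower. Genes at least 2-fold lower numbered 427 and 458 with pseudocounts of 0.1 and 0.01, which shrink falls to low values less, and 101 with a filter at 5 TPM, under which fewer genes (9718) were tested. Among genes with a mean of at least 10 TPM, fewer by construction, 2307 were called lower, 218 were at least 2-fold higher and 54 at least 2-fold lower. Median ratio scaling gave 2999 genes higher and 3159 lower. Leaving out each library in turn gave 4878 to 5968 called genes, 1665 to 2381 higher and 2981 to 3736 lower. No gene called in the reported analysis was called in the opposite direction under any of these alternatives. The 4 named genes kept their direction and call in all 57 fits that held them; G10090_2998 left the fits without 1 cytokine library, since the filter needs 3 libraries at 1 TPM. Of 36 class ratios with 1 library left out, 32 moved by less than the spread of the libraries. Removing the called genes selects on the outcome, tends to bring the ratios of tested classes towards 1 and so tests nothing. It gave 0.992 from 100 to 1000 TPM, against 1.08, and 0.981 from 1 to 10 TPM, against 0.896. The class over 1000 TPM hardly moved, at 0.958 against 0.957. The labels do not say whether the replicate numbers pair the libraries, and the values do not settle it. Same-numbered libraries' deviations from their group means correlated at 0.098, 0.206 and 0.017, and 4 of the 6 correlated best with their own number. With the replicate block, 6644 genes were called. The 36 gene lists could not be tested under any setting. The unknown depth limits what can be said of genes under 1 TPM.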

Other observations

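The tests of weakly expressed genes below were chosen after the result was seen, whereas those of chance and of scaling were chosen before. A group of 238 entries carries identifier numbers apart from all others, from 48145 to 50348, while the rest end at 34016. These entries were weak, with a median of 0.205 TPM against 8.72 TPM for the rest, and held 0.0578% of the TPM total. Of the 65 among the tested genes, 6 were called higher and 23 lower with the cytokines, so 44.6% were called. Of the other 11557 tested genes, 2231 were called higher and 3729 lower (51.6% called). What kind of transcript the numbers mark is not given in the sources used here.

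The real grouping called 5989 genes. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many, the real one. The other 9 splits each called 0 genes in limma at an adjusted p under 0.05, and at most 222 genes at an unadjusted p under 0.05, against 6621 for the real split. Each of the other splits puts libraries of both groups on both sides, so that a real difference between the groups becomes spread within them and few calls are expected whatever its cause. With 10 splits the share also cannot fall under 0.1, so this comparison does not decide whether the calls arose by chance.

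Weakly expressed genes were lower in the cytokine libraries, at 0.748 ± 0.062 of the control level from 0.1 to 1 TPM. Were the deposited TPM unbiased at low counts, lower depth of the cytokine libraries would add zeros but leave this ratio near 1. All 3 libraries lay below 1 (0.702 to 0.819). The depth, the quantification tool and any filter on genes are unknown, so this does not exclude lower depth. The cytokine library with the fewest zeros (1993) also had the highest ratio (0.819). A larger share of the TPM total taken by the risen genes would lower every class alike, yet the ratio relative to that of the class from 10 to 100 TPM was 0.745 ± 0.051. An even background in the controls would be limited to about the level of the weakest class, 0.0379 TPM. That class was chosen for low values in these same libraries, so the limit is not firm. The class from 0.1 to 1 TPM dropped by 0.111 ± 0.028 TPM, or by 0.1005 ± 0.0282 TPM among its 2268 genes that were not called, which include those not tested. An effect of the cytokines on rarely transcribed genes may account for the pattern and stays open, untested. Lower depth also stays open, as do an uneven background such as unspliced RNA and RNA of other cells, which need gene names.

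More genes were called lower than higher, 3752 against 2237. Whether scaling between libraries accounts for this stays open. After median ratio scaling 48.7% of the calls were higher (47.5% to 50.8% with 1 library left out), against 37.4% as deposited, but this scaling sets the change of the typical gene near 0 (median log2 fold change -0.0645 before and -0.0081 after), which largely fixes an even split, so the comparison decides nothing. Whether weak genes are the whole of it cannot be told, since among genes with a mean of at least 10 TPM the share higher was 43.0% as deposited (39.6% to 49.7% with 1 library left out) and 40.7% after quantile normalization (40.5% to 42.0%), but 56.6% after median ratio scaling (56.5% to 57.3%), which the same centring affects. Quantile normalization gives every library the same distribution of values, so its share does not decide this either. The excess of rises among changes of at least 2-fold did not depend on that scaling, with 351 rises and 118 falls after it, but with a pseudocount of 0.1 there were 393 rises and 427 falls.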
